A study of Homo sapiens with 15 samples.

How the data were processed

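DNA methylation was measured by capture bisulfite sequencing in 15 samples of hTERT-HME1, a human mammary epithelial cell line immortalised with telomerase. In bisulfite sequencing an unmethylated cytosine is read as thymine and a methylated one as cytosine, and the capture step, the SureSelectXT Methyl-seq kit per the labels' protocols, restricts the reads to selected genome regions, here called targets. Cells had been transfected with a control siRNA or with an siRNA against BRCA2, a gene of homologous recombination repair, and grown with or without epidermal growth factor (EGF). Per the labels, the 3 groups were control siRNA with EGF (7 samples), BRCA2 siRNA with EGF (4 samples) and BRCA2 siRNA without EGF (4 samples). The labels also give the siRNA sequence (control-1, control-2, control-3, BRCA2-1 or BRCA2-2), the passage number (10 or 3) and a biological replicate letter (A or B). Passage 10 holds 4 of the controls and 2 of the BRCA2 siRNA samples with EGF, passage 3 holds the remaining 5 samples with EGF, and all 4 samples without EGF were at passage 10. Replicate numbers within a group follow the order of deposit and only name a sample. No control siRNA sample without EGF was analysed here, so a difference of the samples without EGF from the controls joins the BRCA2 siRNA and the medium.

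The submitters' processing notes list Trim Galore 0.4.1, BSMAP 2.89, Picard 1.92 and the genome build hg19, without the role or the order of the tools. For each sample the authors deposited, per the file headers, the read counts of every CpG on target (all reads, methylated reads, and the same for each strand) and the methylation level as a fraction. The deposited fraction differed from methylated over all reads by at most 0.0005, which is the rounding. A second deposited table gave the methylation fraction of 146514 targets in each sample. That fraction differed by at most 0.0005 from the unweighted mean over the CpGs of a target with at least 5 reads in that sample. Other steps of the authors are not given in the sources used here. Coordinates are hg19 as deposited, with the start of each target raised by 1 to count from 1. No genome sequence was used, so the offset of the deposited positions was not tested.

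The read total over CpGs ranged from 88518837 (control siRNA replicate 6) to 229512817 (control siRNA replicate 5), over 4190035 to 4448758 CpGs per sample, with a median of 14 to 34 reads per CpG. Reads are not independent molecules where PCR copies remain, so errors from read counts cover counting only. Of 4660290 CpGs seen in any sample, the 2214955 CpGs with at least 10 reads in all 15 samples were kept. A target was tested when it held at least 3 such CpGs, which left 128549 targets (87.74%) with a median of 7 CpGs, a median length of 678 bp and a median of 346 reads per target and sample (113 to 2089 from the 10th to the 90th percentile). The level of a target is methylated over all reads, summed over its CpGs. Target levels of any pair of samples correlated with r between 0.992 and 0.996 across targets, which are not independent replicates. Read counts of same-group, same-passage samples differed by more than sampling noise (mean chi-square per target 1.427 to 1.799, where sampling alone gives 1), which separate libraries and PCR copies also give. Every sample counted as 1 replicate by design. The labels name biological replicates A and B at passage 10. At passage 3 all 5 samples had letter A and each had another siRNA sequence, so each sequence was read in 1 sample there.

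The following choices were fixed before the data were examined. Methylated and unmethylated reads of each target were fitted with a quasi-binomial logistic model with group and passage as terms over all 15 samples. The dispersion was moderated across targets by empirical Bayes with 1 prior for all targets (11.54 prior and 11 residual degrees of freedom). The plan named a moderated quasi-likelihood F test. The test run divided each difference by its standard error from the moderated dispersion and took a two-sided p from a t distribution. It is called the quasi-binomial test here, and p was adjusted by Benjamini-Hochberg over the 128549 targets. A target is called at an adjusted p under 0.05. The 4 comparisons were BRCA2 siRNA with EGF against control, BRCA2 siRNA without EGF against control, BRCA2 siRNA without against with EGF, and passage 10 against passage 3. Differences are in percentage points between group mean levels adjusted for passage, with the standard error (SE) over samples. The interaction of BRCA2 siRNA with passage and the difference between both BRCA2 siRNA sequences without EGF were tested in the same way. Overall methylation is the mean level over the kept CpGs, each weighted alike, compared by exact two-sided permutation tests. Labels were permuted within passage in the comparison of BRCA2 siRNA with EGF against control, the samples without EGF were compared at passage 10 alone, and the passages were compared among the controls. Region classes were targets with a mean control level under 20%, 20 to 80% or over 80%, and targets with at least 5 or under 5 CpGs per 100 bp. The class tests form 1 family of 20, adjusted by Benjamini-Hochberg.

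Targets are named by a rule: called, with a difference of at least 10 points, with the same sign at every passage where both groups have samples, and among the 10 largest gains or losses. Any other target in the text was chosen after its values were seen. The gene table at hand is for build GRCh38.p14 while the files use hg19, so no target was assigned to a gene. The planned tests of gene lists, of promoter and gene body classes and of genes always to be named were therefore not run, and regions are given by coordinates. The samples are DNA, so the knockdown of BRCA2 was not checked.

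Alternatives fixed before the data were examined were read minimums of 5 and 20, a CpG minimum of 1 or 5 per target, no passage term, autosomes only, passage 10 samples only, the replicate letter as a block, the compared groups only, a difference of at least 10 points, and each sample left out in turn. For overall methylation they were also pooled reads and the mean of the deposited target levels. Further fixed alternatives were edgeR 4.0.16 (quasi-likelihood test on methylated and unmethylated counts) and limma 3.58.1 on log2 odds (0.5 reads added to each count), on the mean of CpG levels and on the deposited levels, all in R 4.3.3.

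Further alternatives were added after the data were seen. The median dispersion was 0.9 in the tenth of targets with the fewest reads and 2.35 in the tenth with the most, so a fit in which the prior dispersion follows the read count was added. The read share of samples along the genome was examined, and fits without both BRCA2-1 siRNA samples without EGF and fits with a read share score as a term were added. The replicate letters were compared at passage 10 in the fit with the letter as a block, and group, passage and letter labels were reassigned within passage 10, within letter or within group. For the read share, each target's share of a sample's reads was compared with the median of the controls on the log2 scale. Medians over 40 bins each of CpG density, methylation level, length and depth were taken out, and the median was taken in 555 autosomal windows of 5 Mb with at least 20 targets of 30 reads or more. A shift was called where both samples of a pair lay beyond 4 control SDs (0.101) on the same side in at least 2 adjacent windows. The call was repeated on the values before these medians were taken out, with their own control SD. Whole chromosomes were compared by the median of their windows.

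The planned test and the fit with the prior following the read count were tried on simulated counts for all 4 comparisons, and edgeR and limma for passage alone. Counts were drawn from the real means and depths, with 200 of 128549 targets changed. The other alternatives were not simulated. For BRCA2 siRNA with EGF against control, the planned test recovered 83% of changes of 10 points and 99% of changes of 20 points. It recovered 75% and 98% for BRCA2 siRNA without EGF against control, 66% and 95% for BRCA2 siRNA without against with EGF, and 79% and 100% for passage. Among unchanged targets in the passage simulation, 5.23% had an unadjusted p under 0.05, but 10.68% did in the tenth of targets with the most reads, so p-values of the deepest targets are too small. With the prior following the read count that share was 6.29%, and with edgeR 5.87%. With limma it was 2.41% on log2 odds and 2.58% on percent levels, so limma is too strict at the deepest targets. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.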

Results

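CpG methylation was measured in 15 samples of the mammary epithelial line hTERT-HME1 at 128549 captured targets, which hold the CpGs read at least 10 times in every sample. The groups were control siRNA with EGF (n = 7), BRCA2 siRNA with EGF (n = 4) and BRCA2 siRNA without EGF (n = 4). Each sample held between 88518837 and 229512817 reads over CpGs, and the median target had 346 reads in a sample. At this depth and spread the SE of a difference at a target had a median between 1.09 and 1.38 points in the 4 comparisons. The mean CpG was methylated at 50.73% ± 0.39 (SD, n = 7) in the controls, at 50.93% ± 0.41 (SD, n = 4) in BRCA2 siRNA cells with EGF and at 50.98% ± 0.18 (SD, n = 4) in BRCA2 siRNA cells without EGF.

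The first comparison asked how methylation in cells transfected with BRCA2 siRNA differed from control cells when both had EGF. Overall methylation was 0.24 points higher with BRCA2 siRNA within passage (exact permutation p = 0.08 over 150 assignments, n = 4 and 7). At passage 10 the level was 51.23% ± 0.36 (SD, n = 2) with BRCA2 siRNA and 51.02% ± 0.21 (SD, n = 4) with control siRNA, and at passage 3 it was 50.63% ± 0.08 (SD, n = 2) and 50.35% ± 0.03 (SD, n = 3). At passage 3 both BRCA2 siRNA samples (50.57% and 50.68%) lay above all 3 controls (50.32% to 50.37%). Overall methylation also differed between the replicate letters at passage 10, where A lay above B by 0.11 to 0.51 points in all 5 pairs of the same siRNA and medium (exact sign test p = 0.0625). The BRCA2 siRNA difference was therefore also taken within letter, and it was 0.29 points for letter A (n = 1 and 2) and 0.13 points for letter B (n = 1 and 2) at passage 10, and 0.28 points at passage 3 (n = 2 and 3), where all samples had letter A. All 4 BRCA2 siRNA samples lay above every control of their passage and letter. With labels permuted within passage and letter, an alternative fixed before the data were examined, the difference was 0.24 points with an exact permutation p = 0.0111, the smallest that 90 assignments can give. Both permutation tests treat samples of the same siRNA sequence as independent, although BRCA2 siRNA replicates 1, 2 and 4 all had BRCA2-2. Their p therefore does not hold for siRNA sequences as the units. The difference was between 0.14 and 0.29 points in the 5 region classes, and none passed the adjustment over 20 class tests (adjusted exact permutation p between 0.2 and 0.306, n = 4 and 7). The class tests permuted labels within passage and were not repeated within letter. Without control replicate 2 the overall difference was 0.28 points (exact permutation p = 0.03, n = 4 and 6), and without BRCA2 siRNA replicate 2 it was 0.35 points (exact permutation p = 0.02, n = 3 and 7). Without BRCA2 siRNA replicate 1 it was 0.15 points (exact permutation p = 0.22, n = 3 and 7).

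No single target was called between BRCA2 siRNA and control siRNA with EGF by the quasi-binomial test (0 of 128549). The unadjusted p was under 0.05 at 7044 targets, where 6427 come from chance alone, and the smallest adjusted p was 0.24. Called targets numbered 0 with edgeR, 0 with each of the 3 limma fits and 0 with the prior following the read count. The middle 95% of differences lay between -2.97 and 3.67 points. Among the targets with the smallest p, chosen after their values were seen, a target of 5 CpGs on chromosome 11 (23561312 to 23561931, hg19) had a level of 18.87% ± 1.60 (SD, n = 4) with BRCA2 siRNA and 11.82% ± 2.15 (SD, n = 7) with control siRNA. A target of 31 CpGs on chromosome 7 (155674154 to 155675212) stood at 86.41% ± 0.34 (SD, n = 4) against 83.72% ± 0.41 (SD, n = 7). Their adjusted p was 0.667 and 0.24 in the quasi-binomial model fitted across all targets. The BRCA2 siRNA difference was also compared between passages, and 0 targets were called (5697 at an unadjusted p under 0.05, smallest adjusted p 0.71, quasi-binomial test alone). Leaving out BRCA2 siRNA replicate 1 or replicate 2 gave 1 call each.

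**Figure D1:**
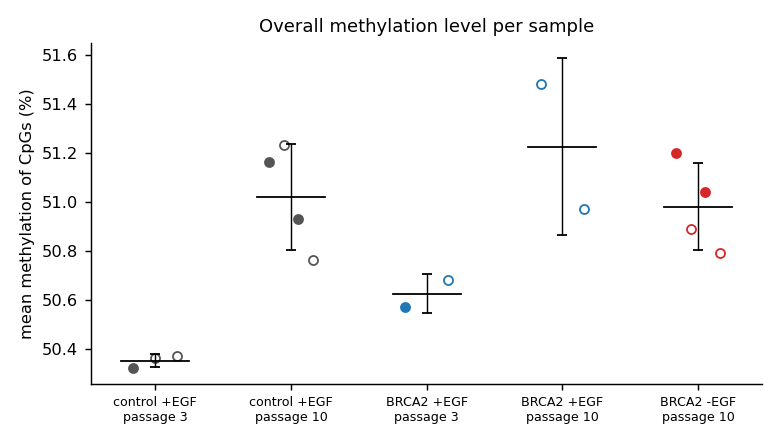
Mean methylation of CpGs in percent for each of the 15 samples, by group and passage; filled symbols are siRNA sequences numbered 1, open symbols the others, and bars give the mean ± SD. The 3 passage 3 controls lie between 50.32% and 50.37%, below the 4 passage 10 controls at 50.76% to 51.23%.

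BRCA2 siRNA cells without EGF were then compared with control siRNA cells with EGF, a comparison that joins the siRNA and the medium. Methylation was lower at 5 targets and higher at 0 of 128549, with differences between -20.78 and -5.61 points. Of these targets 2 were on chromosome 11 and 1 each on chromosomes 8, 4 and X. Overall methylation differed by -0.04 points at passage 10 (exact permutation p = 0.771 over 70 assignments, n = 4 and 4), by -0.15 points within letter A and by 0.07 points within letter B (n = 2 and 2 each). The unadjusted p was under 0.05 at 9331 targets against 6427 expected by chance. With group labels reassigned, the other splits examined gave up to 8591, and up to 8745 among the passage 10 samples. The count of 5 calls depended on the fit. With edgeR 9 targets were called, among them the same 5. With the replicate letter as a block 8 were called (1 of them higher), among them the same 5. With limma 3 were called on log2 odds (1 of them among the 5), 0 on the mean of CpG levels (10123 at an unadjusted p under 0.05) and 0 on the deposited levels (8893). A fit on the compared groups alone called 0 (8904 at an unadjusted p under 0.05), and a fit on passage 10 samples alone called 1. The prior following the read count, added after the data were seen, called 22 (6 of them higher), among them the same 5. Leaving out control replicate 1, 2 or 4 or BRCA2 siRNA without EGF replicate 2 gave 0 calls. There were 2 calls without BRCA2 siRNA without EGF replicate 1 or 3, and 3 calls without control replicate 5 or 6 or BRCA2 siRNA with EGF replicate 2 or 4. With both BRCA2-1 siRNA samples without EGF left out there were 0 calls (8222 at an unadjusted p under 0.05), and with a read share score as a term there were 0 (7714), both alternatives added after the data were seen. The score was built on stretches called in the BRCA2-1 siRNA samples without EGF and was highest in them (0.283 and 0.329). As a term it can therefore take up part of the group difference itself, so its 0 calls do not show what the 5 calls depend on. No target was called between both BRCA2 siRNA sequences without EGF (0 calls, 7826 at an unadjusted p under 0.05, smallest adjusted p 0.363, quasi-binomial test alone).

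The largest loss was at a target of 3 CpGs on chromosome 8 (102019561 to 102020180, hg19, 75 to 215 reads per sample). Its level was 53.60% ± 4.6 (SD, n = 4) without EGF and 75.25% ± 3.00 (SD, n = 7) in the controls, and it was 75.19% ± 4.37 (SD, n = 4) in BRCA2 siRNA cells with EGF. A target of 3 CpGs at 88143130 to 88143661 on chromosome 11 (112 to 305 reads) stood at 34.77% ± 4.52 (SD, n = 4) without EGF, 50.77% ± 2.87 (SD, n = 7) in the controls and 44.80% ± 2.10 (SD, n = 4) in BRCA2 siRNA cells with EGF. Another target of 3 CpGs on chromosome 11 (9775549 to 9776168, 100 to 282 reads) stood at 15.95% ± 1.91 (SD, n = 4), 31.23% ± 3.05 (SD, n = 7) and 26.81% ± 2.63 (SD, n = 4) in the same order. These 3 targets met the naming rule, with differences of -20.78 ± 2.61 (SE), -16.00 ± 2.28 (SE) and -14.99 ± 1.90 (SE) points and adjusted p of 0.0177, 0.0443 and 0.0335 in the quasi-binomial model. The other 2 calls, chosen after their values were seen, were smaller differences over more CpGs. A target of 19 CpGs on chromosome 4 (6955189 to 6956220, 738 to 2147 reads) differed by -5.86 ± 0.74 points (SE, adjusted p = 0.0177), with 16.98% ± 1.34 (SD, n = 4) without EGF and 22.05% ± 1.54 (SD, n = 7) in the controls. A target of 46 CpGs on chromosome X (10587940 to 10589301, 1782 to 5027 reads) differed by -5.61 ± 0.92 points (SE, adjusted p = 0.0177), with 21.94% ± 0.62 (SD, n = 4) without EGF and 26.56% ± 1.61 (SD, n = 7) in the controls. At the chromosome X target, BRCA2 siRNA cells with EGF stood at 23.11% ± 2.45 (SD, n = 4). All 4 samples without EGF lay below the mean of the controls at all 5 targets. The targets were called for a lower level in these same samples, so this adds no support. The chromosome 4 target lies in a stretch (0 to 10 Mb) where both BRCA2-1 siRNA samples without EGF had a lower share of reads than the controls (-0.165 and -0.215 on the log2 scale). Both BRCA2-2 siRNA samples without EGF also had a lower share there (-0.199 and -0.088) and along the whole of chromosome 4 (-0.121 and -0.066).

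**Figure D2:**
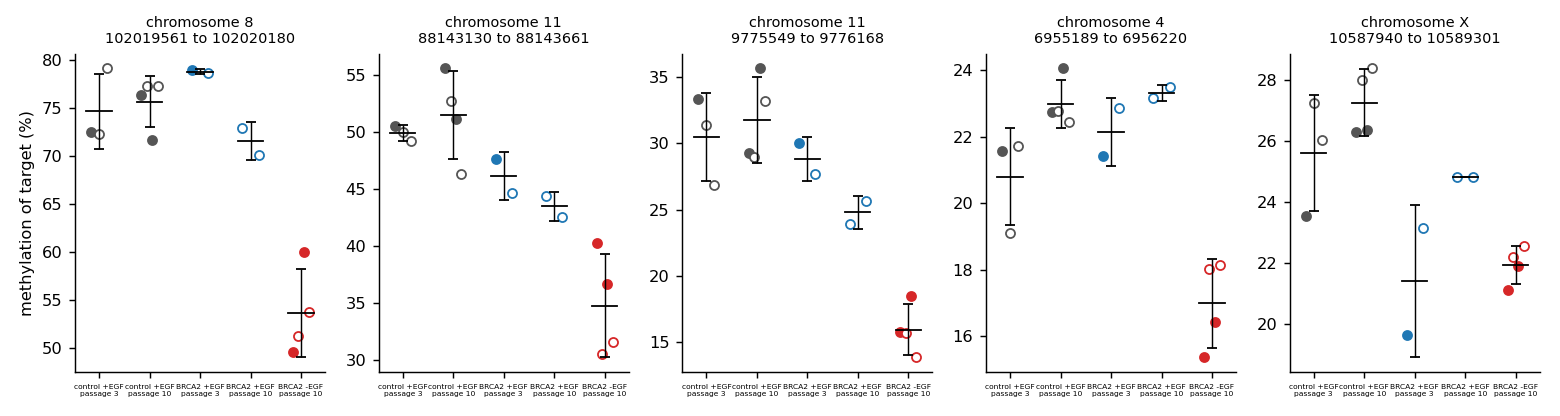
Methylation level in percent of the 5 targets called between BRCA2 siRNA cells without EGF and controls, for each of the 15 samples by group and passage; filled symbols are siRNA sequences numbered 1, open symbols the others, and bars give the mean ± SD. At the chromosome 8 target the samples without EGF average 53.60% and the controls 75.25%.

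BRCA2 siRNA cells without and with EGF were compared to ask about the medium. The siRNA sequences were not matched: both passage 10 samples with EGF had BRCA2-2, and of the 4 samples without EGF 2 had BRCA2-1 and 2 had BRCA2-2. At passage 10 overall methylation was 50.98% ± 0.18 (SD, n = 4) without EGF and 51.23% ± 0.36 (SD, n = 2) with EGF. The difference of -0.25 points had an exact permutation p = 0.333 (n = 4 and 2), where 15 assignments allow no p below 0.0667. It was -0.43 points within letter A and -0.06 points within letter B (n = 2 and 1 each). With BRCA2-2 siRNA on both sides, an alternative added after the data were seen, it was -0.39 points (exact permutation p = 0.333, the smallest that 6 assignments can give; n = 2 and 2), and both samples without EGF (50.89% and 50.79%) lay below both with EGF (51.48% and 50.97%). No target was called by the quasi-binomial test (0 calls, smallest adjusted p 0.0775), and 8291 had an unadjusted p under 0.05 against 6427 expected by chance. With both BRCA2-1 siRNA samples without EGF left out, 0 were called as well (8287 at an unadjusted p under 0.05). Among the targets with the smallest p, chosen after their values were seen, the chromosome 4 target at 6955189 to 6956220 stood at 22.74% ± 0.92 (SD, n = 4) with EGF and 16.98% ± 1.34 (SD, n = 4) without. A target of 5 CpGs on chromosome 15 (39166495 to 39167114, hg19) stood at 15.43% ± 2.38 (SD, n = 4) and 6.93% ± 1.10 (SD, n = 4), with an adjusted p of 0.115 in the quasi-binomial model. Called targets numbered 0 with edgeR and 0 with each of the 3 limma fits, 3 with a read minimum of 20, 2 with the replicate letter as a block and, in the fit added after the data were seen, 4 with the prior following the read count. Leaving out BRCA2 siRNA with EGF replicate 1 or 4 gave 1 call each, and leaving out BRCA2 siRNA without EGF replicate 4 gave 3. The overall difference was 0.01 points without BRCA2 siRNA with EGF replicate 1.

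Passage 10 was compared with passage 3 among the cells with EGF. The passages were not matched for siRNA sequence. Only passage 3 held control-2, and its BRCA2 siRNA samples had BRCA2-1 and BRCA2-2, while those of passage 10 had BRCA2-2 alone. Methylation was higher at passage 10 at 1083 targets and lower at 42, which makes 1125 called targets. The mean CpG was methylated at 51.02% ± 0.21 (SD, n = 4) in passage 10 controls and 50.35% ± 0.03 (SD, n = 3) in passage 3 controls, a difference of 0.67 points (exact permutation p = 0.0286 over 35 assignments, the smallest p they can give; n = 4 and 3). Within letter A, the only letter at passage 3, the difference was 0.84 points (n = 2 and 3). Passage 10 controls of letter B averaged 50.85% (n = 2), also above the passage 3 controls but below those of letter A. The labels do not say whether letter A means the same at both passages. The differences were small, with a median size of 2.81 points among the called targets and 1.1 to 5.16 points from the 10th to the 90th percentile. Of the called targets, 735 had a control level of 20 to 80%, 291 a level under 20% and 99 a level over 80%. The number of called targets depended on the fit. An unadjusted p under 0.05 was found at 15304 targets against 6427 expected by chance. With passage labels reassigned, the other splits examined gave up to 12755, and up to 14015 within each group. With edgeR 215 targets were called (207 higher), 213 of them among the 1125. With the replicate letter as a block 1408 were called (1339 higher), among them the same 1125. With limma 108 were called on the mean of CpG levels (102 higher, 76 of them among the 1125), 0 on log2 odds (12698 at an unadjusted p under 0.05) and 0 on the deposited levels (11118 at an unadjusted p under 0.05). The prior following the read count, added after the data were seen, called 589 (560 higher, 567 of them among the 1125), and 176 targets were called by it, by edgeR and by the planned test. Leaving out control replicate 5 gave 416 calls, control replicate 2 gave 661 and BRCA2 siRNA with EGF replicate 1 gave 714. With any 1 control left out the overall difference was 0.6 to 0.75 points, with exact permutation p of 0.0667 or 0.1 that so few samples cannot bring below 0.05. With pooled reads it was 0.66 points (exact permutation p = 0.0857, n = 4 and 3), and with the deposited target levels 0.47 points (exact permutation p = 0.0571, n = 4 and 3). The labels give no preparation date, so passage cannot be told apart from a batch that follows it.

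The replicate letters at passage 10 were compared at single targets after the data were seen, with group in the fit. Between letters A and B 55 targets were called (40 higher with A, 10144 at an unadjusted p under 0.05; n = 5 and 5). The count was lower with any 1 sample left out: 40, 37, 23 and 17 without control replicates 1, 2, 3 and 4, 25 and 36 without BRCA2 siRNA with EGF replicates 1 and 2, and 27, 31, 46 and 18 without BRCA2 siRNA without EGF replicates 1, 2, 3 and 4. Each group at passage 10 held as many samples of letter A as of letter B.

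CpG dense targets, those with at least 5 CpGs per 100 bp, made up 576 of the 1125 called targets (51.2%) and 10.08% of all tested targets, and 569 of the 576 were higher at passage 10. Dense targets also had more reads, with a median of 1771 against 315 in the others, and targets with as many reads as the called ones were dense in 37.0%. Dense targets made up 45.12% of the targets called by edgeR where 33.17% follow from their read counts, and 49.92% against 33.49% with the prior following the read count. These shares were described without a test. In the controls the mean level of dense targets was 33.83% ± 0.23 (SD, n = 4) at passage 10 and 32.93% ± 0.05 (SD, n = 3) at passage 3, and that of the others 58.26% ± 0.22 (SD, n = 4) and 57.68% ± 0.02 (SD, n = 3). By level class the difference was 1.01 points at targets of 20 to 80%, 0.51 points under 20% and 0.35 points over 80%. None of the 5 class differences passed the adjustment over 20 class tests (adjusted exact permutation p of 0.191 or 0.2, n = 4 and 3). The 35 assignments allow no unadjusted p below 0.0286, which 3 of the 5 classes reached, so these 5 could not pass by themselves.

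The targets named by the rule were 2 gains and 3 losses. A target of 5 CpGs on chromosome 7 (22484728 to 22485347, hg19) was higher at passage 10 by 10.64 ± 1.82 points (SE, adjusted p = 0.0329), with 36.68% ± 2.88 (SD, n = 4) in passage 10 and 25.56% ± 4.66 (SD, n = 3) in passage 3 controls. A target of 9 CpGs on chromosome 19 (2607553 to 2608172) was higher by 10.54 ± 3.28 points (SE, adjusted p = 0.0397). In the controls it stood at 45.16% ± 3.43 (SD, n = 4) and 40.25% ± 4.63 (SD, n = 3), with overlapping values, and in BRCA2 siRNA cells at 52.97% ± 0.48 (SD, n = 2) and 32.78% ± 5.59 (SD, n = 2). The losses were at chromosome 1 (208352445 to 208353110, -13.16 ± 2.27 points, adjusted p = 0.0368), chromosome 5 (80313976 to 80314642, -11.25 ± 2.23 points, adjusted p = 0.00895) and chromosome 3 (23846335 to 23847789, -10.27 ± 1.68 points, adjusted p = 2.46e-04). Errors are SE and adjusted p is from the quasi-binomial model. The smallest p-values, chosen after they were seen, belonged to long targets with many CpGs. A target of 318 CpGs on chromosome 18 (55103054 to 55109374) stood at 25.31% ± 0.29 (SD, n = 4) in passage 10 and 22.23% ± 0.28 (SD, n = 3) in passage 3 controls, and in BRCA2 siRNA cells at 25.91% ± 1.03 (SD, n = 2) and 22.48% ± 0.19 (SD, n = 2). A target of 208 CpGs on chromosome 3 (147136206 to 147142590) stood at 44.07% ± 0.78 (SD, n = 4) and 38.35% ± 0.40 (SD, n = 3) in the controls, and a target of 182 CpGs on chromosome 4 (20252930 to 20257064) at 24.42% ± 0.21 (SD, n = 4) and 19.29% ± 0.95 (SD, n = 3). Their adjusted p was 2.28e-07, 2.43e-06 and 2.43e-06 in the quasi-binomial model, which gives p-values that are too small at targets with many reads.

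**Figure D3:**
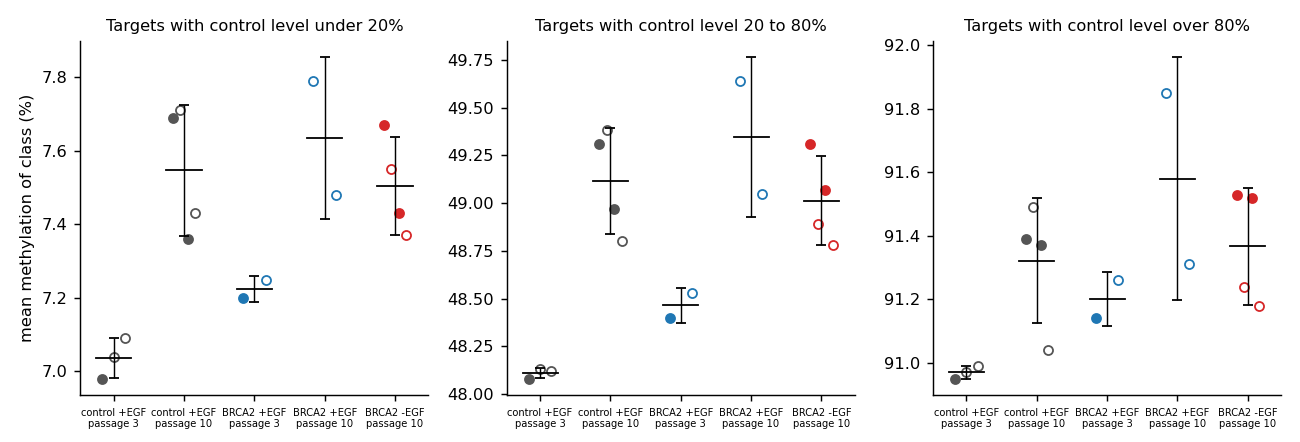
Mean methylation in percent of targets with a control level under 20%, of 20 to 80% and over 80%, for each of the 15 samples by group and passage; filled symbols are siRNA sequences numbered 1, open symbols the others, and bars give the mean ± SD, with a separate axis range in each panel. In targets of 20 to 80% the controls average 49.12% at passage 10 and 48.11% at passage 3.

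The read counts were also compared along the genome, a look at the data that was added after they were seen. Both BRCA2-1 siRNA samples without EGF (replicates 1 and 3) shared 4 stretches, 9 windows of 5 Mb in all, where their share of reads differed from the controls. On the log2 scale the share was lower on chromosome 4 from 0 to 10 Mb (-0.165 and -0.215), on chromosome 6 from 95 to 105 Mb (-0.161 and -0.172) and on chromosome 17 from 0 to 15 Mb (-0.117 and -0.167), and higher on chromosome 12 from 125 to 135 Mb (0.135 and 0.144). In the BRCA2-2 siRNA samples without EGF (replicates 2 and 4) the same stretches stood at -0.199 and -0.088 on chromosome 4, -0.078 and 0.004 on chromosome 6, -0.046 and 0.006 on chromosome 17, and 0.072 and -0.02 on chromosome 12. The controls lay between -0.077 and 0.047 on the chromosome 4 stretch and between -0.032 and 0.038 on the chromosome 12 stretch. The SD of control windows was 0.025. Before the 4 target properties were taken out it was 0.034, and 2 of the 4 stretches were called, those on chromosomes 6 and 12. Such a stretch was found in 0 of the other 4 pairs that shared the siRNA sequence and medium at passage 10, and in 2 of the 100 remaining pairs of samples, with at most 2 windows. Across all 555 windows, letters A and B correlated with r = 0.644 for BRCA2-1 siRNA without EGF. For BRCA2-2 siRNA r was 0.589 without EGF and 0.575 with EGF, and in the control pairs -0.071 and -0.251. Each control was compared with the other controls alone, which can change r by itself. The BRCA2 siRNA samples were all compared with the same control medians, which can raise r by itself.

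**Figure D4:**
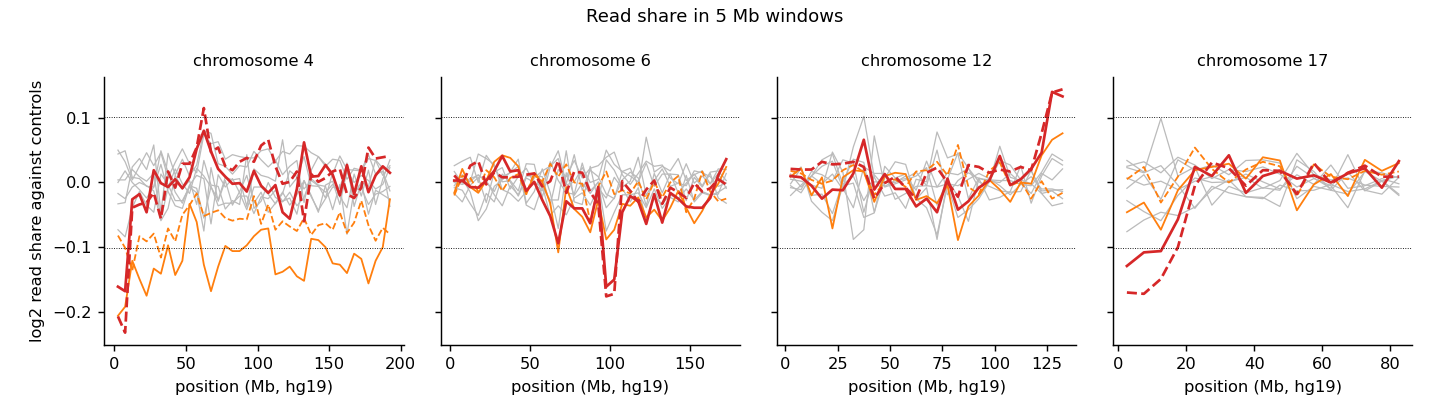
Log2 share of reads against the median of the controls in windows of 5 Mb along chromosomes 4, 6, 12 and 17 (hg19), for the 7 controls (grey), BRCA2-1 siRNA without EGF (red) and BRCA2-2 siRNA without EGF (orange), with replicate letter A solid and B dashed and dotted lines at ±0.101, which is 4 control SDs. Both red lines leave the dotted range in the 4 stretches, and the orange lines lie below 0 along chromosome 4, with medians of -0.121 and -0.066.

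The 4 stretches also moved together in the other 13 samples, where the chromosome 12 stretch ran against the mean of the other 3 with r = -0.91 (permutation p = 4e-05, 1 relation tested). Spearman's rho was -0.89 (permutation p = 1.1e-04), and r was -0.83 without the 2 samples farthest from the median. The stretches were summed up in a read share score, the chromosome 12 stretch minus the mean of the other 3. It was 0.283 and 0.329 in the BRCA2-1 siRNA samples without EGF, 0.180 and 0.006 in the BRCA2-2 siRNA samples without EGF, and between -0.074 and 0.093 in the controls. In BRCA2 siRNA cells with EGF it was 0.107 in replicate 3, the only BRCA2-1 siRNA sample with EGF, and -0.064, -0.014 and -0.048 in the BRCA2-2 siRNA samples (replicates 1, 2 and 4). Replicate 3 lay on the same side as the BRCA2-1 siRNA samples without EGF in all 4 stretches, with -0.06 on chromosome 4, -0.039 on chromosome 6, 0.057 on chromosome 12 and -0.051 on chromosome 17. Control replicates 3 and 6 and BRCA2 siRNA without EGF replicate 2 also lay on that side in all 4, with scores of 0.047, 0.093 and 0.180. Across the 13 samples other than the BRCA2-1 siRNA samples without EGF, the score rose with the second principal component of target methylation, which holds 9.68% of the variance (r = 0.89, permutation p = 7e-05, adjusted p = 1.4e-04 over 4 relations). Spearman's rho was 0.79 (permutation p = 0.002), and r was 0.81 without the 2 samples farthest from the median score. Within the 7 controls r was 0.78 (exact permutation p = 0.021, adjusted p = 0.028 over 4 relations), Spearman's rho was 0.71 (exact permutation p = 0.088) and r was 0.70 without the 2 farthest.

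**Figure D5:**
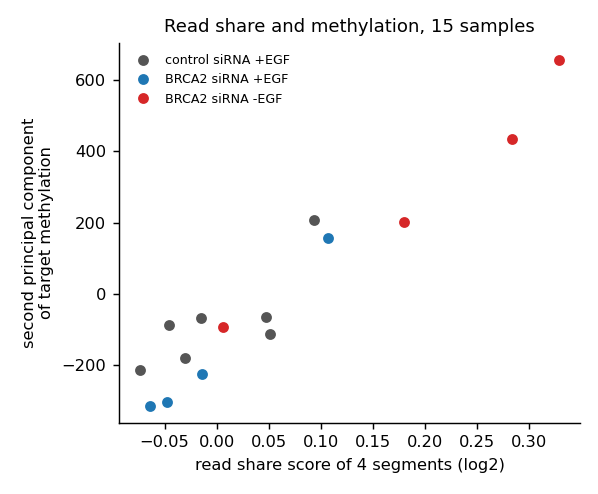
Second principal component of target methylation (vertical, arbitrary units) against the read share score of the 4 stretches (horizontal, log2) for each of the 15 samples, coloured by group. The samples without EGF have scores of 0.283, 0.180, 0.329 and 0.006, the BRCA2-1 siRNA sample with EGF has 0.107, and the controls lie between -0.074 and 0.093.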

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

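Planned were the search for samples far from the others, the splits that ignore passage and letter, the counts of the 4 comparisons with 1 sample left out, with the letter as a block and with edgeR and limma. All other tests in this part were chosen after the results were seen.

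Of 66 groups of values examined for a sample far from the others, 1 stood out, where chance gives 3.3. Control siRNA replicate 5 had 229512817 reads over CpGs (229.51 M), the most of its group of 7, and the next had 148285491. This sample was at passage 3, and without it 416 instead of 1125 targets differed between the passages.

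In 9 windows of 5 Mb both BRCA2-1 siRNA samples without EGF had a share of reads beyond the range of the controls. Capture bias with CpG density, methylation level, length or depth of the targets is argued against as the whole cause on chromosomes 6 and 12 alone, where the stretches were also called before these were taken out and 89.3% of their mean shift was left (0.171 before and 0.153 after on the log2 scale); it stays open on chromosomes 4 and 17, since the 4 stretches were called on corrected values and the 100% left in them (0.16 before and after) decides nothing. Of the 546 windows outside the stretches, 0.92% followed them with an absolute r over 0.7, where chance gives 0.73%. The 4 target properties had been taken out beforehand, so variation of the whole library along them could not show. Read share also correlated across all windows between letters A and B of the same BRCA2 siRNA and medium (r = 0.575 to 0.644). All BRCA2 siRNA samples were set against the same control medians, which can give a positive r by itself, so this r decides nothing. Variation of the whole library therefore stays open. That the stretches move together in both samples alone is argued against by r = -0.91 between the stretches in the other 13 samples. An added shift private to both samples stays open. Their scores were 0.283 and 0.329, and the highest other was 0.180, in BRCA2 siRNA without EGF replicate 2. Read counting alone stays open as well. The read share score followed the second principal component of methylation (r = 0.89), but both came from the same libraries. Sequencing depth stays open, with r = -0.36 between the score and the log2 number of reads over 15 samples (permutation p = 0.18, adjusted p = 0.18 over 4 relations, Spearman's rho -0.46 with permutation p = 0.086, r = -0.36 without the 2 farthest). A copy number difference in part of the cells may account for the shifts, with 1 of 2 copies more or less in a mean of 21.4% of cells (15.6% to 27.7%), but any shift of this size would allow such a share, so this was not a test that could exclude it.

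The higher methylation at passage 10 was weighed against 2 technical explanations. Incomplete bisulfite conversion adds most to unmethylated CpGs, but the gain of targets of 20 to 80% exceeded that of targets under 20% by 0.49 points in the controls (exact permutation p = 0.0286, n = 4 and 3), which argues against it as the whole cause. A preparation batch that coincides with passage cannot be told apart from passage, since the labels name none, and passage 10 controls with letter A lay 0.35 points above those with letter B, against 0.67 points between the passages. Time in culture stays open as an untested biological explanation.

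Other splits of the samples into groups of the same sizes were compared with the real one. For passage, 100 of the 462 possible splits of the 11 samples with EGF were examined. Of these 1 gave as many calls, the real one with 1125, and the highest other gave 78. Within each group 100 of the 210 possible splits were examined, and 1 gave as many, the real one. The highest other gave 619, a split with all 5 passage 3 samples on the same side. That split is also among the 462, so 78 is not the highest of them. These splits treat letters A and B of an siRNA sequence as independent, so they do not exclude chance. The count was 416 without control replicate 5, 661 without control replicate 2 and 714 without BRCA2 siRNA with EGF replicate 1.

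For the letters A and B at passage 10, 1 of 36 splits within group gave as many calls, the real one with 55, and the highest other gave 2. The comparison was chosen after the data were seen, and 1 of 36 is the smallest share it can give. It therefore does not exclude chance. The count without 1 sample was 40, 37, 23 and 17 without control replicates 1 to 4, 25 and 36 without BRCA2 siRNA with EGF replicates 1 and 2, and 27, 31, 46 and 18 without BRCA2 siRNA without EGF replicates 1 to 4. The letters also differed in the share of reads on the plus strand. It was 1.8% to 1.86% in the passage 10 samples of letter A and 1.58% to 1.68% in those of letter B. At passage 3 it was 1.58% to 1.71%. This share describes the sequenced reads, so a preparation batch that follows the letters is possible. Whether the letters stand for cultures or for a preparation batch stays open, and each group at passage 10 held both alike.

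For BRCA2 siRNA without EGF against control, 100 of the 330 possible splits of the 11 samples, which ignore passage, were examined. Of these 1 gave as many calls, the real one with 5, and the highest other gave 3. Of the 70 splits of the 8 passage 10 samples, 2 gave as many calls as the real 5, the other being letter B against A, the highest with 10. Within letter 1 of 36 splits gave as many calls, the real one, with 5 against a highest other of 2, and with the letter as a block also 1 of 36, with 8 against 2. These splits treat letters A and B of an siRNA sequence as independent, so they do not exclude chance. With the samples of an siRNA sequence kept together, 1 of 6 splits gave as many (5 against 0), too few for a share under 0.05, and without both BRCA2-1 siRNA samples without EGF the count was 0 (8222 at an unadjusted p under 0.05). Called targets numbered 0 instead of 5 without control replicate 1, 2 or 4 or BRCA2 siRNA without EGF replicate 2, 2 without BRCA2 siRNA without EGF replicate 1 or 3, and 3 without control replicate 5 or 6 or BRCA2 siRNA with EGF replicate 2 or 4.

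For BRCA2 siRNA with EGF against control the real count was 0 (1 without BRCA2 siRNA with EGF replicate 1 or 2; quasi-binomial test, 0 with edgeR and limma), so all 100 of 100 splits gave as many calls whatever the cause, and this decides nothing. The highest other gave 2. By targets at an unadjusted p under 0.05, 14 of 100 splits gave as many as the real 7044, and the highest other gave 8624.

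For BRCA2 siRNA without against with EGF the real count was also 0 (1 without BRCA2 siRNA with EGF replicate 1 or 4, 3 without BRCA2 siRNA without EGF replicate 4; quasi-binomial test, 0 with edgeR and limma), so all 35 of 35 splits gave as many and this decides nothing either. The highest other gave 1. By targets at an unadjusted p under 0.05, 1 of 35 splits gave as many, the real one with 8291, and the highest other gave 8210. These splits ignore passage and siRNA sequence.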

How the results depend on the processing

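Alternatives with the prior following the read count, a read share score as a term or both BRCA2-1 siRNA samples without EGF left out were chosen after seeing the data, all others before. The cause of each change below was not tested, except where fewer samples or targets entered. The read share score was built on stretches called in the BRCA2-1 siRNA samples without EGF. As a term it can take up part of a difference of the samples without EGF.

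For BRCA2 siRNA with EGF against control, all 16 alternatives gave 0 called targets, and leaving out 1 sample gave 0 to 1 (1 without BRCA2 siRNA with EGF replicate 1 or 2).

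For BRCA2 siRNA without EGF against control, 3 of 17 alternatives stayed within 1.5 times the 5 calls. The others gave 3 calls with differences of at least 10 points, 3 with a read minimum of 20, 2 with at least 5 CpGs per target, 3 on autosomes, 1 with passage 10 samples only, 0 with the compared groups only, 3 with limma on log2 odds, 0 with limma on the mean of CpG levels, 0 with limma on deposited levels, 9 with edgeR, 22 with the prior following the read count, 0 without both BRCA2-1 siRNA samples and 0 with the read share score as a term. Leaving out 1 sample gave 0 to 7 (0 without control replicate 1, 2 or 4 or BRCA2 siRNA without EGF replicate 2, 2 without BRCA2 siRNA without EGF replicate 1 or 3, 3 without control replicate 5 or 6 or BRCA2 siRNA with EGF replicate 2 or 4).

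For BRCA2 siRNA without against with EGF, 14 of 17 alternatives gave 0 calls. A read minimum of 20 gave 3 and the prior following the read count gave 4, and leaving out 1 sample gave 0 to 3 (1 without BRCA2 siRNA with EGF replicate 1 or 4, 3 without BRCA2 siRNA without EGF replicate 4).

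For passage, 8 of 14 alternatives stayed within 1.5 times the 1125 calls. The others gave 5 calls with differences of at least 10 points, 0 with limma on log2 odds, 108 with limma on the mean of CpG levels, 0 with limma on deposited levels, 215 with edgeR and 589 with the prior following the read count. Leaving out 1 sample gave 416 to 1237 (416 without control replicate 5, 661 without control replicate 2, 714 without BRCA2 siRNA with EGF replicate 1). A fit without the passage term or on passage 10 samples only gives no passage value.

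Deviations over all targets correlated with a mean of 0.015 in pairs of the same letter and -0.015 in pairs of different letters, none over 0.1. The planned fit has no letter term. With the letter as a replicate block, 8 targets were called for BRCA2 siRNA without EGF against control, 2 for without against with EGF, 0 for BRCA2 siRNA with EGF against control and 1408 for passage, and the overall difference of BRCA2 siRNA with EGF from control was 0.24 points with an exact permutation p = 0.0111. That permutation treats samples of the same siRNA sequence as independent.

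Without leaving out single samples, the overall difference of BRCA2 siRNA with EGF from control passed 0.05 only with the block above, and that of BRCA2 siRNA without EGF from control passed it in no alternative. For BRCA2 siRNA without against with EGF no p below 0.0667 was possible, so p says nothing on stability there. The sign of BRCA2 siRNA without EGF against control turned with the mean of deposited target levels (0.02 points). Without both BRCA2-1 siRNA samples without EGF it was -0.18 points from control (exact permutation p = 0.267) and -0.39 points from BRCA2 siRNA with EGF (exact permutation p = 0.333). Passage gave 0.66 points with pooled reads (exact permutation p = 0.0857) and 0.47 with the mean of deposited target levels (exact permutation p = 0.0571). Leaving out 1 sample gave 0.15 to 0.35 points for BRCA2 siRNA with EGF against control (0.28 without control replicate 2, 0.35 without BRCA2 siRNA with EGF replicate 2 and 0.15 without its replicate 1, the exact permutation p being 0.03, 0.02 and 0.22), -0.13 to 0.03 for BRCA2 siRNA without EGF against control (0.01 without control replicate 1, 0.03 without control replicate 2, 0.02 without BRCA2 siRNA without EGF replicate 4), -0.5 to 0.01 for without against with EGF (0.01 without BRCA2 siRNA with EGF replicate 1) and 0.6 to 0.75 for passage, where p cannot go below 0.05. Of the 20 class tests 0 passed, also with classes from the mean of all samples, but the few assignments left the passage classes unable to pass by themselves. Gene list and annotation alternatives were not run. Depth limited which targets were tested, 128549 of 146514. A change of 10 points was recovered in 66% to 83% of simulated targets, depending on the comparison.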

Other observations

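The test of the passage gain without EGF was planned before its result was seen, and all other relations in this part were chosen after the data were seen.

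Methylation and read share were related within the controls too, by the read share score and the second principal component of methylation. Pearson's r was 0.78 (exact permutation p = 0.021, adjusted p = 0.028 over 4 relations), but Spearman's rho was 0.71 (exact permutation p = 0.088). Within the controls alone, the chromosome 12 stretch ran against the other 3 with r = -0.95 (exact permutation p = 0.0016, Spearman's rho -0.95 with exact permutation p = 0.0032, n = 7, r = -0.97 without the 2 farthest). The data do not show whether the read share changed through the siRNA, the medium or chance.

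Chromosome 4 as a whole had a lower share of reads in both BRCA2-2 siRNA samples without EGF, with medians over its windows of -0.121 and -0.066 on the log2 scale, where the 7 controls lay between -0.021 and 0.038. The chromosome 4 stretch of the read share score is part of it. In both passage 10 BRCA2-2 siRNA samples with EGF the medians were -0.053 and -0.049, inside the limit of 0.055 set by 4 control SDs. The BRCA2-1 siRNA samples without EGF stood at -0.001 and 0.017. Chromosome 18 stood at -0.061 in BRCA2 siRNA with EGF replicate 1, where the controls lay between -0.040 and 0.047. These were the 3 of 330 values past the limit over 22 chromosomes and 15 samples, and none was a control.

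A smaller passage gain in cells without EGF was tested as a hypothesis. At 1181 targets chosen as gaining methylation with passage in the controls, the samples without EGF lay -0.17 points from passage 10 BRCA2 siRNA samples with EGF, relative to all targets (exact permutation p = 0.2, n = 4 and 2, too few to go below 0.0667). At 381 targets chosen in BRCA2 siRNA samples with EGF, they lay -0.54 points from passage 10 controls (exact permutation p = 0.0857, n = 4 and 4). The gains with passage in the reference samples were 1.20 and 1.64 points. Neither test decides whether the gain was smaller without EGF.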
